A study of Homo sapiens with 6 samples.

How the data were processed

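RNA was measured in A549 cells, an established human lung adenocarcinoma line, after heating, X-irradiation or both. Per the labels' protocols, the cells first grew for 24 h at 37 °C. Heated cells then spent 1 h at 41.5 °C or 44 °C and returned to 37 °C for 3 h. Irradiated cells received 3 Gy of X-rays and were kept for 3 h at 37 °C. Cells given both treatments were irradiated straight after the heat, and since the time they were then kept is not stated, 3 h was assumed. For the control no time after the first 24 h is given, so a difference from it may include time in culture. The 6 arrays form 6 groups of 1 array each: an untreated control, radiation alone, each temperature alone, and each temperature followed by radiation. Nothing in the sources used here says that the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

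Per the labels' protocols, 300 ng of total RNA per sample was turned into biotin-labelled DNA through random priming and amplification by in vitro transcription. Per the submitters' processing notes, the arrays were read with Affymetrix Expression Console 1.1 and summarised by RMA, which corrects the background, equalises the distributions between arrays and combines the probes of a feature. The deposited values are on the log2 scale, as the authors normalized them. The sorted values of each array deviated from the mean of the 6 by at most 0.11 on the log2 scale, so the distributions were close but not identical. The genome build behind the probes is not given in the sources used here.

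The value table holds 53617 features. The platform annotation names exactly 1 gene symbol for 16098 of them (30.0%) and several for 0, and 37519 are unnamed here. All 16098 were matched to gene identifiers of the RefSeq table of assembly GRCh38.p14, which changed 0 symbols. That table was also used to find which gene a microRNA lies in, by position without regard to strand, and no coordinate is given. For the 779 genes with several features, the feature with the highest mean over the 6 arrays was used, which left 14884 genes. Among called genes with several features, another feature had the opposite sign for 13 of 59 genes at 44 °C against 37 °C, for 5 of 29 at 41.5 °C against 37 °C and for 22 of 90 at 44 °C against 41.5 °C. Unnamed features entered no comparison of genes or lists and were tested in a separate fit of all 53617 features. Genes of near-identical sequence, such as HSPA1A and HSPA1B or members of the snoRNA and SNAR families, can share probe signal and are uncertain as single genes. An array feature named for a microRNA gene does not tell the mature microRNA from its longer precursors.

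With 1 array per group, a difference between 2 groups has no replicate check. Tests therefore came from an additive model fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with temperature as a factor and radiation as a term, which gives 2 arrays at each temperature and 3 with and 3 without radiation. The 2 residual degrees of freedom hold any interaction of heat and radiation as well as noise. Variances were moderated with an intensity trend (prior degrees of freedom 8.06, median residual SD 0.113). P-values are two-sided and adjusted by Benjamini-Hochberg over the 14884 genes, and a gene was called at an adjusted p under 0.05. The median standard error of a log2 difference was 0.138 between temperatures and 0.113 for radiation. The number of arrays limits this precision.

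Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 25 lists with at least 5 measured members. Of the 29 fixed lists, 4 fell below that minimum: proteasome subunits with 0 members, fibroblast markers with 3, and replication-dependent histones and mitochondrially encoded genes with 0 each. With a correlation estimated for each list, 0 list calls held in any comparison, and fry, which asks only whether the genes of a list move one way, was run as another test. Counts of list members are given over all genes and adjusted over the list alone. Differences between single arrays were counted at 2-fold and above and carry no test. For these, a list median was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins, which do not keep the correlation between the genes of a list. A departure from additivity is the log2 value of the combined treatment minus heat alone, minus radiation alone, plus the control.

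The named genes follow a rule. For each model comparison they are the 12 largest rises and 10 largest falls among called genes with the same sign in every pair of arrays. Free places went to the genes with the largest smallest-pair difference. To these come the 2 highest and 2 lowest members of each list, a short set of heat shock, p53 and immediate early genes, and the 5 highest and 5 lowest departures at each temperature among genes above the median level. Of the short set, HSPA8, DNAJB1, HSP90AA1, CDKN1A, MDM2 and BTG2 were not analysed here. The groups, the model, the tests, the lists, this rule and the other settings to be tried, apart from those named as added, were fixed before the data were examined.

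The alternatives were a further quantile normalization, median centring, removal of the genes with a mean level under 4.56 (leaving 9922 genes), the mean of a gene's features, moderation without the trend or with robust estimation, a model without the radiation or temperature term, only the 4 arrays of the temperatures compared, other thresholds, and each array left out in turn. A refit without 1 array keeps 1 residual degree of freedom, and an array left alone in its temperature is assumed to vary like the others. A refit without both 44 °C arrays, and a test of the radiation response at 44 °C against that at the lower temperatures, were added after the data were seen.

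The model was tested on simulated data built on the 14884 genes, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. It recovered 16% and 73% of them for 44 °C against 37 °C, 23% and 84% for 41.5 °C against 37 °C, and 46% and 98% for radiation. False calls were 5 of 94, 1 of 108 and 3 of 147. With camera, simulated lists of 54, 53 and 55 genes moved by 1 on the log2 scale were recovered, and unchanged lists of 25 genes were not called. The simulated noise was drawn independently for each gene and array from the model's own variances, with no interaction of heat and radiation. The residuals of the data hold that interaction, so these shares do not measure what could be recovered in the data, above all for radiation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 and pandas 2.3.3.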

Results

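Transcript levels were measured on 6 Affymetrix arrays of A549 cells, a human lung cancer line, to compare heating, X-irradiation and their combination. There was 1 array in each group: untreated cells at 37 °C (control), 3 Gy of X-rays alone, 1 h of heat at 41.5 °C, 1 h at 44 °C, and each heating followed by 3 Gy. Each array gave 53617 values on the log2 scale, with medians from 4.39 in the control and the 41.5 °C array to 4.46 in the 44 °C array. Correlations across all features between pairs of arrays were highest for 44 °C with and without radiation (Pearson r = 0.989) and lowest for the 44 °C array and the combined 41.5 °C array (r = 0.970). Features are not independent replicates, so these correlations only describe the arrays.

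Set against the control, 260 genes differed at least 2-fold after 44 °C, 190 of them higher, and 248 after 44 °C with radiation, 192 of them higher. After 41.5 °C the count was 67, with 34 higher, and with radiation added it was 110, with 67 higher. Radiation alone gave 40, with 27 higher. These counts compare pairs of single arrays and have no replicate check. At 3-fold they were 73, 69, 4, 7 and 0 in the same order, and at 2-fold without the dimmest genes 181, 175, 28, 68 and 9.

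**Figure D1:**
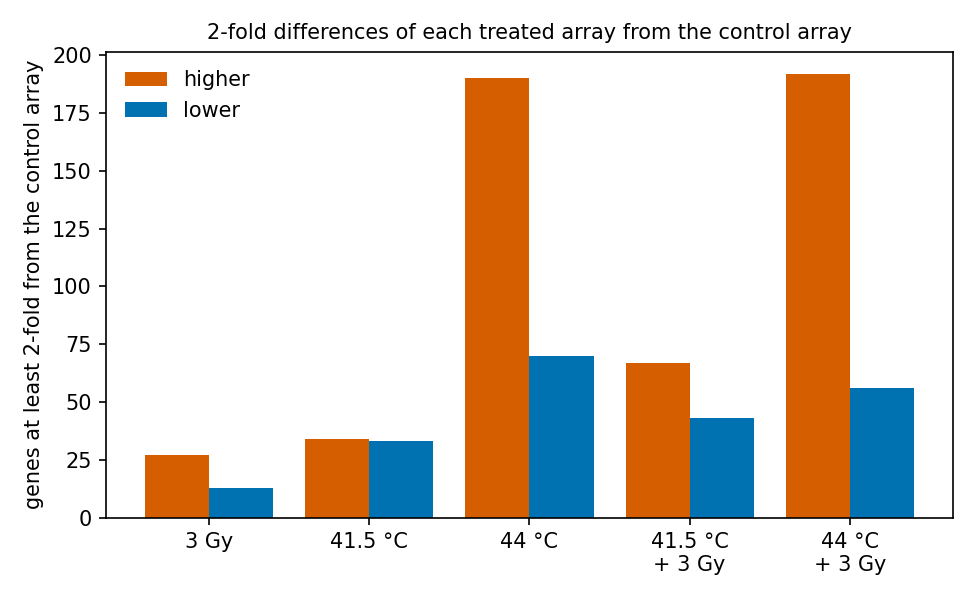
Number of genes at least 2-fold higher or at least 2-fold lower than in the control array, for each of the 5 treated arrays (x axis: array; y axis: genes of 14884, 1 array per group, no test). Both arrays heated to 44 °C reach about the same number of higher genes (190 and 192), above the 27 after radiation alone.

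The comparison of 44 °C with 37 °C asked which transcripts differed after 1 h of severe heat. EGR1, an immediate early transcription factor, had the largest rise: its log2 level was 5.26 in the control and 5.36 in the irradiated array, against 10.88 and 10.85 in the 44 °C arrays without and with radiation. That is 46.9-fold, or 5.55 ± 0.09 on the log2 scale (SE, 2 arrays at each temperature, adjusted p = 3.9e-10 in limma). Other members of the same class rose as well, FOSB 17.5-fold and FOS 4.36-fold. Among the chaperones, HSPA6, a strictly stress-inducible HSP70, rose 9.26-fold and CHORDC1, a partner of HSP90, rose 8.01-fold. MIR27B, whose microRNA lies in a cluster with MIR23B, fell by 2.95 ± 0.14 on the log2 scale, and MIR21, a microRNA abundant in many tumours, was 4.69-fold lower.

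In all, 910 genes were called at 44 °C, of which 532 rose and 378 fell, and 192 of them differed at least 2-fold (163 rose and 29 fell). The further largest rises were PNLDC1, an exonuclease that trims small RNAs (28.0-fold), LOC100507412, VHLL, MIR4521, BCL2L15 of the BCL2 family, the antisense RNAs PARD6G-AS1 and IDI2-AS1, and ZNF10, a zinc finger repressor. Their log2 rises lay between 4.81 for PNLDC1 and 2.76 for ZNF10. The further largest falls were MIR1206, MIR548L, ZNF767P, MIR23B, MIR545, LINC00173, L3HYPDH and LOC389906, from -1.73 for MIR1206 to -1.34 for LOC389906. All 12 of the largest rises and 10 of the largest falls stayed called when any 1 of the 6 arrays was left out. The total was 263 (233 rose, 30 fell) without the control and 271 (210 rose, 61 fell) without the irradiated array, and 405 (311 rose, 94 fell) with moderation that ignored the intensity trend. The balance of rises and falls depended on scaling: a further quantile normalization gave 486 rises and 599 falls, and median centring gave 467 and 538.

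Of the 15 measured heat shock chaperones and co-chaperones, 14 rose over all genes and 15 adjusted over the list alone, with a median of 1.59 on the log2 scale. HSPA1B rose 6.35-fold and HSPA1A 5.58-fold, although the sequences of this HSP70 pair are near identical and their signals are not separable. BAG3, a co-chaperone that links HSP70 to autophagy, rose 5.06-fold, HSPH1 of the HSP110 family rose by 1.59 ± 0.07 and HSPB1, a small heat shock protein, by 0.81 ± 0.07. HSPA4 did not pass over all genes (0.26 ± 0.08, adjusted p = 0.0915), and neither did HSF1, the regulator of these genes and not a member of the list (-0.13 ± 0.10, adjusted p = 0.543). The list was shifted upward (camera, adjusted p = 9.5e-36), with adjusted p = 0.133 with an estimated correlation. Of 20 immediate early genes, 12 rose and 0 fell over all genes, 14 and 0 adjusted over the list alone, with a median of 0.86. ATF3, a stress-induced repressor, rose by 1.80 ± 0.18, whereas the values of IER3 (-0.05) and DUSP2 (0.03) did not pass, and that of DUSP2 changed sign under both other scalings. This list had adjusted p = 6.0e-23, and adjusted p = 0.160 with an estimated correlation.

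**Figure D2:**
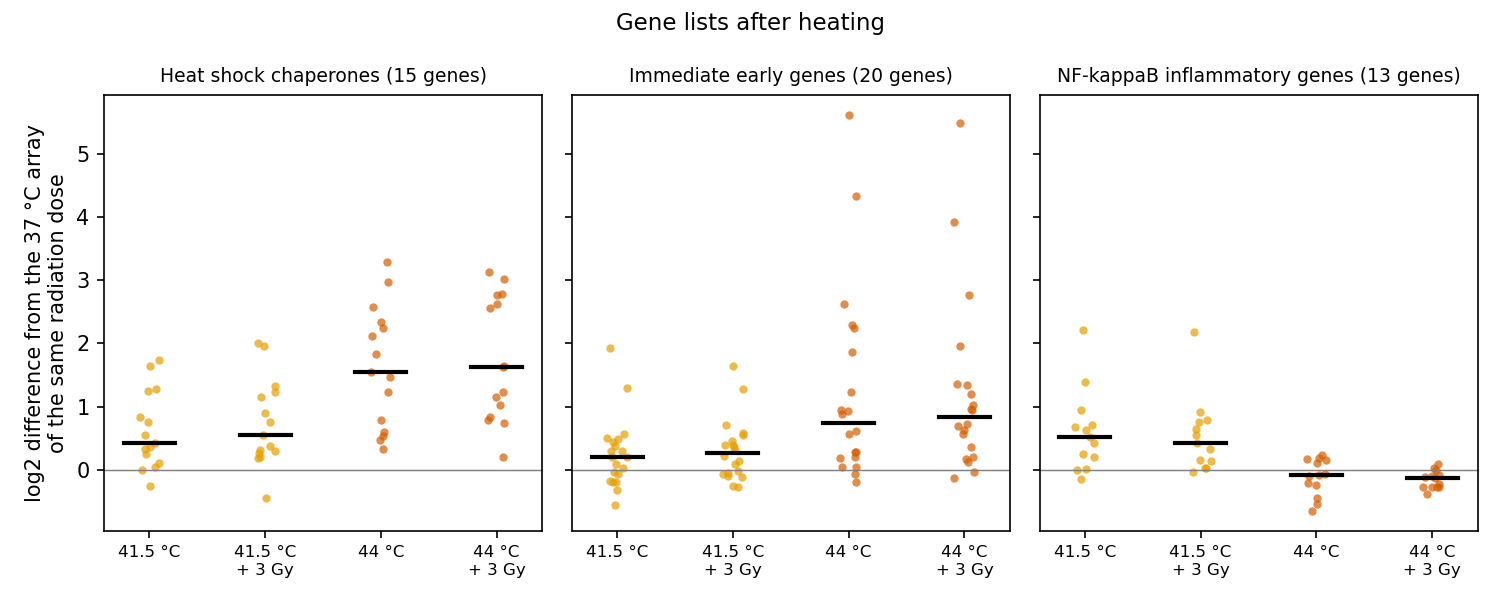
Each point is 1 gene's log2 difference between a heated array and the 37 °C array of the same radiation dose (y axis), for heat shock chaperones (15 genes), immediate early genes (20) and NF-kappaB inflammatory genes (13), with a black bar at the median (x axis: heated array). The heat shock median was 1.55 and 1.62 at 44 °C without and with radiation, against 0.43 and 0.55 at 41.5 °C, while the inflammatory median was 0.53 and 0.43 at 41.5 °C and -0.07 and -0.13 at 44 °C.

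Genes of homologous recombination and the Fanconi pathway, which repair DNA breaks and crosslinks, were lower at 44 °C: all 14 had negative values, 2 fell over all genes and 8 adjusted over the list alone, with a median of -0.31 (adjusted p = 4.3e-05, and adjusted p = 0.350 with an estimated correlation). XRCC2, a recombination gene, fell by 0.48 ± 0.10, a call lost without the irradiated array (adjusted p = 0.268) or the combined 44 °C array. EXO1, a resection exonuclease, fell by 0.41 ± 0.08, a call lost without any of the 4 arrays at 37 °C and 44 °C (up to adjusted p = 0.214). Of 54 cytosolic ribosomal protein genes, 11 rose and 0 fell, 14 and 1 adjusted over the list alone, with a median of 0.09 (adjusted p = 4.3e-05, and adjusted p = 0.483 with an estimated correlation). FAU, a ribosomal protein fused to a ubiquitin-like domain, rose by 1.29 ± 0.11. Of 10 TGF-beta and BMP targets, 4 rose and 1 fell on either adjustment, with a median of 0.21 (adjusted p = 0.00148, and adjusted p = 0.483 with an estimated correlation). SNAI1, a repressor of epithelial genes, rose by 2.27 ± 0.13.

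Among 12 genes of the integrated stress response, 4 rose and 1 fell on either adjustment (median 0.11, adjusted p = 0.0458, and adjusted p = 0.483 with an estimated correlation). DDIT3, a pro-apoptotic factor also known as CHOP, rose by 1.21 ± 0.14. This list's call was lost without the control (adjusted p = 0.0586) and without the irradiated array (adjusted p = 0.0936), and after a further quantile normalization (adjusted p = 0.0590). Of 23 small nucleolar and Cajal body RNAs, 2 rose and 0 fell, 2 and 2 adjusted over the list alone (median 0.12, adjusted p = 0.0448, and adjusted p = 0.483 with an estimated correlation). SCARNA9 rose by 0.79. Without the irradiated array the adjusted p of this list was 0.389, without the combined 44 °C array 0.122, and after a further quantile normalization 0.0552.

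The other 18 lists were not called by camera at 44 °C. Some of their members rose, such as the survival factor MCL1 (1.22 ± 0.08) and the pro-apoptotic BCL2L11 (1.30 ± 0.14) in a BCL2 family of 14 with 3 rises and 0 falls (median -0.03, adjusted p = 0.164). The median lay below 0 there while the test pointed up. In the hypoxia list 3 of 12 rose, including ANKRD37 (1.64), and in the cholesterol list 2 of 13 rose and 1 fell, the rises including INSIG1, a brake on sterol synthesis (1.00). Of 18 interferon-stimulated genes 2 rose, including ISG20 (1.08). The medians of these 3 lists were 0.04, 0.02 and 0.03, with adjusted p = 0.159, 0.399 and 0.282, and each changed sign under at least 1 other scaling. The p53 targets had 1 rise and 1 fall of 19 (median -0.20, adjusted p = 0.357) and the G2/M genes 0 calls of 26 (median -0.01, adjusted p = 0.666). Without the 44 °C array that had no radiation, the p53 median was -0.27 (adjusted p = 2.2e-08) and the G2/M median 0.21 (adjusted p = 9.3e-08), and the hypoxia list was called as well (adjusted p = 0.0203). Without the combined 44 °C array, the p53 median was 0.15 (adjusted p = 0.0178) and the G2/M median -0.25 (adjusted p = 7.4e-05), each in the opposite direction, and the BCL2 list (adjusted p = 0.00855), the leukocyte markers (adjusted p = 0.0370) and the non-homologous end joining genes (adjusted p = 0.0304) were called.

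The remaining lists had few or 0 calls at 44 °C. The G1/S genes had 2 rises and 4 falls of 26 (median -0.14, adjusted p = 0.159, although fry called this list downward at adjusted p = 0.0222), and the NF-kappaB list 0 rises and 1 fall of 13 (median -0.09, adjusted p = 0.176). The unfolded protein response (0 of 10, adjusted p = 0.518), NRF2 targets (0 of 7, adjusted p = 0.423), end joining genes (0 of 7, adjusted p = 0.112) and metallothioneins (0 of 9, adjusted p = 0.839) had no called member. Mitochondrial chaperones and proteases had 1 rise of 7, HSPD1, at 0.69 (adjusted p = 0.921 for the list), and the zinc finger genes 15 rises and 16 falls of 491 (adjusted p = 0.816). Markers of other cell types were the endothelial ones (0 of 6, adjusted p = 0.921) and the leukocyte ones (1 of 5, median 0.11, adjusted p = 0.0599). Alveolar and keratin markers (0 of 13, adjusted p = 0.875) and housekeeping genes (0 of 6, adjusted p = 0.628) were not called. Adjusted over the list alone, rises and falls were 3 and 5 for p53 targets, 3 and 6 for G1/S genes, 4 and 2 for cholesterol genes, 3 and 1 for hypoxia genes, 2 and 1 for interferon-stimulated genes, 1 and 1 for mitochondrial chaperones, 2 and 0 for leukocyte markers and 17 and 16 for zinc finger genes, and as over all genes for the other lists not called.

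The comparison of 41.5 °C with 37 °C asked the same of mild heat. CCL2, a chemokine that attracts monocytes, had the largest rise: its log2 level was 8.15 in the control and 8.26 in the irradiated array, against 10.37 and 10.45 in the 41.5 °C arrays without and with radiation. The rise was 4.59-fold, or 2.20 ± 0.07 on the log2 scale (SE, 2 arrays at each temperature, adjusted p = 5.3e-07). HSPA1B rose 3.65-fold, HSPA1A 3.49-fold and HSPH1 by 1.21 on the log2 scale. FOSL1, a partner of JUN in AP-1, rose 3.46-fold and JUN by 1.29. MMD, a membrane protein of macrophage differentiation, fell by 0.96.

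In all, 489 genes were called at 41.5 °C, with 325 rises and 164 falls, and 29 differed at least 2-fold (22 rose, 7 fell). With moderation that ignored the intensity trend, the count was 9 (8 rose, 1 fell). The other genes among the 12 largest rises were TRIML2, FJX1, the cytoskeletal regulator NAV3, MICB, a ligand of natural killer cells, IRAK2, a kinase below the interleukin-1 receptor, and SNAR-H. The others among the 10 largest falls were BCL6, a transcriptional repressor, RASSF9, BMP4, a BMP ligand, LINC00173, PHF21A, HILPDA, MIR1185-2, MIR4277 and NEIL1, a DNA glycosylase. Of the 12 rises 10 stayed called when any 1 array was left out, and of the 10 falls 1 did, that of MMD. The others were lost without the irradiated array or the control, with the highest adjusted p at 0.0630 for NAV3 and SNAR-H, 0.0761 for BCL6, 0.0501 for PHF21A and up to 0.394, for NEIL1. NEIL1 and MIR4277 were also lost without the 41.5 °C array, and MIR4277 and MIR1185-2 without the combined 41.5 °C array. The total was 19 without the irradiated array, 38 without the control and 212 without the combined 41.5 °C array, and it was 800 and 788 without the 44 °C array and the combined 44 °C array. A further quantile normalization gave 273 rises and 229 falls.

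Of the 15 heat shock genes, 8 rose and 0 fell at 41.5 °C, 11 and 1 adjusted over the list alone, with a median of 0.43 (adjusted p = 6.8e-15, and adjusted p = 0.274 with an estimated correlation). HSPB1 rose by 0.83 and BAG3 by 1.09, the call of BAG3 being lost without the irradiated array (adjusted p = 0.0630), whereas the values of HSPA6 (0.18, adjusted p = 0.546) and CHORDC1 (-0.35, adjusted p = 0.0805) did not pass over all genes. Of 13 inflammatory targets of NF-kappaB, 6 rose and 0 fell, 8 and 0 adjusted over the list alone, with a median of 0.43 (adjusted p = 4.3e-09, and adjusted p = 0.274 with an estimated correlation). Besides CCL2, CXCL8, the neutrophil chemokine interleukin-8, rose by 1.09 ± 0.18. The call of CXCL8 was lost without the control (adjusted p = 0.175), the irradiated or the 41.5 °C array. Of 20 immediate early genes, 5 rose and 0 fell, 8 and 1 adjusted over the list alone, with a median of 0.15 (adjusted p = 2.1e-04, and adjusted p = 0.469 with an estimated correlation). EGR1 (0.04), FOS (-0.30) and ATF3 (0.14) did not pass.

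NRF2 targets, which serve antioxidant defence, had 3 rises and 0 falls of 7 at 41.5 °C, 4 and 0 adjusted over the list alone, with a median of 0.32 (adjusted p = 5.3e-04, and adjusted p = 0.469 with an estimated correlation). SRXN1, which repairs oxidised peroxiredoxins, rose by 0.97. Of 26 G2/M genes 0 passed on either adjustment, although 24 had negative values, with a median of -0.26 (adjusted p = 2.9e-05, and adjusted p = 0.742 with an estimated correlation). This rested on the combined 41.5 °C array, without which the median was -0.0046 and the adjusted p 0.731, with the test pointing up. The zinc finger genes had 20 rises and 4 falls of 491, 25 and 4 adjusted over the list alone (median 0.06, adjusted p = 0.0135, and adjusted p = 0.469 with an estimated correlation). Their call was lost without the irradiated array (adjusted p = 0.0839) and the 41.5 °C array (adjusted p = 0.0535). Ribosomal protein genes had 2 rises and 0 falls of 54 on either adjustment (median 0.06, adjusted p = 0.0261, and adjusted p = 0.655 with an estimated correlation). That call was lost without the control (adjusted p = 0.0519), the irradiated array (adjusted p = 0.0839) or the combined 41.5 °C array (adjusted p = 0.258), and after a further quantile normalization (adjusted p = 0.226). The other 18 lists were not called by camera, with adjusted p from 0.0839 to 0.992. Fry called the G1/S genes upward among them (median 0.04, adjusted p = 0.0102). Without the 41.5 °C array that had no radiation, the p53 targets (adjusted p = 1.5e-04) and the BCL2 family (adjusted p = 0.00376) were called, both upward, and without the combined 41.5 °C array the p53 targets were called downward (median -0.16, adjusted p = 0.00797).

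The temperatures were also compared directly. EGR1, FOSB and CHORDC1 were higher at 44 °C than at 41.5 °C, by 5.51, 4.05 and 3.35 on the log2 scale, and HSPA6 was 8.15-fold higher. CLK1, a kinase of splicing factors, was higher by 2.72 and TSPYL2 by 2.69. CCL2 was 5.42-fold lower at 44 °C, its log2 level there being 7.95 and 7.99 without and with radiation, CCL20, a chemokine for dendritic and T cells, fell by 1.27 and MIR21 fell by 2.64.

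In all, 1805 genes were called between 44 °C and 41.5 °C, of which 729 were higher and 1076 lower at 44 °C, and 225 differed at least 2-fold (154 higher, 71 lower). Besides EGR1, FOSB, CHORDC1, HSPA6, CLK1 and TSPYL2, the 12 largest rises held PNLDC1, LOC100507412, VHLL, BCL2L15, PARD6G-AS1 and BTK, a tyrosine kinase of B cells. Besides CCL2 and MIR21, the 10 largest falls held MIR27B, MIR1206, MIR548C, LOC389906, MIR23B, the pseudogene AADACP1, MIR548L and L3HYPDH. All of these stayed called when any 1 array was left out. The total was 1024 without the combined 41.5 °C array and 1137 (567 higher, 570 lower) without the 44 °C array, and 791 (397 higher, 394 lower) with moderation that ignored the intensity trend. Median centring gave 580 higher and 1432 lower.

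Of the 15 heat shock genes 11 were higher and 0 lower at 44 °C than at 41.5 °C on either adjustment (median 0.68, adjusted p = 2.5e-13, and adjusted p = 0.231 with an estimated correlation). BAG3 was higher by 1.25, while the value of HSPB1 was -0.02 (adjusted p = 0.918). Of 20 immediate early genes 11 were higher and 2 lower, 14 and 3 adjusted over the list alone (median 0.41, adjusted p = 1.2e-10, and adjusted p = 0.231 with an estimated correlation). FOS was higher by 2.42 and FOSL1 fell by 0.81. Of 13 inflammatory targets of NF-kappaB, 0 were higher and 8 lower, 9 lower adjusted over the list alone (median -0.63, adjusted p = 2.1e-07, and adjusted p = 0.231 with an estimated correlation). CCL2 and CCL20 were among them. NRF2 targets had 0 higher and 4 lower of 7 on either adjustment (median -0.32, adjusted p = 3.7e-04, and adjusted p = 0.351 with an estimated correlation), and OSGIN1, an oxidative stress response gene, fell by 1.06.

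Of 26 G1/S and replication genes 1 was higher and 7 lower, 1 and 9 adjusted over the list alone (median -0.17, adjusted p = 0.00605, and adjusted p = 0.351 with an estimated correlation). MCM10, a replication initiation factor, fell by 0.67, while CCNE1, which drives entry into S phase, was higher by 0.66. Of 14 recombination genes 0 were higher and 3 lower, 1 and 7 adjusted over the list alone (median -0.25, adjusted p = 0.0143, and adjusted p = 0.351 with an estimated correlation). EXO1 fell by 0.74. The list's call was lost without the 41.5 °C array (adjusted p = 0.102) and without the 44 °C array (adjusted p = 0.0648). Of 26 G2/M genes 4 were higher and 0 lower on either adjustment (median 0.25, adjusted p = 2.2e-04, and adjusted p = 0.664 with an estimated correlation). Without the combined 41.5 °C array the median was 0.015 (adjusted p = 0.991), and without the combined 44 °C array it was -0.017 (adjusted p = 0.905) with the test pointing up.

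Of 12 hypoxia and glycolysis genes 5 were higher and 2 lower at 44 °C than at 41.5 °C on either adjustment (median 0.27, adjusted p = 0.00605, and adjusted p = 0.409 with an estimated correlation), a call lost without the combined 44 °C array (adjusted p = 0.0656). ANKRD37 was higher by 1.52, while ADM, the vasodilator adrenomedullin, fell by 0.74. Zinc finger genes had 11 higher and 65 lower of 491, 18 and 73 adjusted over the list alone (median -0.10, adjusted p = 0.0225, and adjusted p = 0.351 with an estimated correlation), a call lost without the 41.5 °C array (adjusted p = 0.0627) and the 44 °C array (adjusted p = 0.0717). TGF-beta and BMP targets had 3 higher and 1 lower of 10, 4 and 1 adjusted over the list alone (median 0.09, adjusted p = 0.0457, and adjusted p = 0.409 with an estimated correlation). Their call was lost without the control (adjusted p = 0.0519), the irradiated array (adjusted p = 0.0515) or the combined 44 °C array (adjusted p = 0.137). Small nucleolar and Cajal body RNAs had 5 higher and 1 lower of 23, 6 and 2 adjusted over the list alone (median 0.17, adjusted p = 0.0498, and adjusted p = 0.409 with an estimated correlation). Theirs was lost without the control (adjusted p = 0.0594), the irradiated array (adjusted p = 0.0597), the 41.5 °C array (adjusted p = 0.141) or the combined 44 °C array (adjusted p = 0.130). The other 14 lists were not called by camera, with adjusted p from 0.0557 to 0.847. Fry called the integrated stress response upward among them (median 0.12, adjusted p = 0.0376, against 0.0913 in camera). The p53 targets were called downward without the 41.5 °C array (median -0.30, adjusted p = 1.4e-04) and without the 44 °C array (median -0.35, adjusted p = 2.5e-08), as were, upward, the cholesterol genes without the 41.5 °C array (adjusted p = 0.0473) and the integrated stress response (adjusted p = 0.0291) and the ribosomal protein genes (adjusted p = 0.0171) without the combined 41.5 °C array. The ribosomal protein genes were also called after a further quantile normalization (adjusted p = 0.0392), without the dimmest genes (adjusted p = 0.0469) and with robust moderation (adjusted p = 0.0453).

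Both temperatures against 37 °C shared 84 rises and 24 falls, where independent lists of these sizes would share 11.6 and 4.17, and 18 genes were called in opposite directions. Unchanged groups simulated against the same arrays had 0.1 and 0 calls at 44 °C and 41.5 °C on average over 20 runs, so their 0 shared calls do not measure the effect of the shared arrays. At an unadjusted p under 0.05 in both comparisons and with 1 direction, the simulated groups shared 171.85 genes on average, against 686 in the data. These 2 counts are not alike, because 744.2 genes would pass in each comparison without any change. In the data 3054 passed at 44 °C and 2545 at 41.5 °C. The gap therefore does not measure the effect of the shared arrays either. Part of the excess over independence may come from the shared 37 °C arrays.

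The comparison of 3 Gy with 0 Gy asked which transcripts differed after X-rays, over the 3 temperatures together. Genes activated by p53 had higher values and genes of G2 and mitosis lower values, in every member measured. All 19 p53 targets were higher, with a median of 0.48 on the log2 scale, among them TP53INP1, a promoter of p53-dependent death (1.18 ± 0.21, SE, 3 arrays against 3), SESN1, a regulator of mTORC1 under stress (0.95), GDF15, a stress cytokine (0.87), and BBC3, the death factor PUMA (0.56). All 26 G2/M genes were lower, with a median of -0.32, among them CENPA, the centromeric histone (-0.66), and the mitotic kinesin KIF14 (-0.51). PURPL, a noncoding RNA of the p53 pathway, had 0.95 ± 0.10.

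Over all 14884 genes, limma called 0 genes for radiation, and 733 had an unadjusted p under 0.05, where 744.2 would be met by chance. The lowest adjusted p was 0.0562, that of PURPL, which passed after median centring. Adjusted over the list alone, 18 of the 19 p53 targets rose and 13 of the 26 G2/M genes fell. The p53 list was shifted upward (camera, adjusted p = 5.5e-33) and the G2/M list downward (adjusted p = 1.8e-26), with adjusted p = 0.673 with an estimated correlation for both. The metallothioneins, which bind zinc and other metals, had 7 higher and 2 lower values of 9, with a median of 0.20 (adjusted p = 0.00267, and adjusted p = 0.673 with an estimated correlation) and 0 calls on either adjustment, MT1B having 0.47 and MT1E 0.37. Their call was lost without the control (adjusted p = 0.129), the irradiated array (adjusted p = 0.128) or the combined 44 °C array (adjusted p = 0.0521). By fry, the p53 and G2/M lists were not called (adjusted p = 0.627 for both), and the 1 list that was, downward, held the G1/S genes (median -0.04, adjusted p = 0.0180, against 0.211 in camera). The other 22 lists were not called by camera, with adjusted p from 0.0643 for the BCL2 family to 0.841. Among other genes with 1 sign in all 3 pairs, MIR620 had 1.09, MIR3928 0.89, KRTAP5-3 0.89, GAS6-AS1 0.75 and AQP7, a glycerol channel, 0.74, whereas MIR3913-1 had -0.99, MIR454 -0.57 and RP9 -0.47.

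Leaving out either 44 °C array removes that temperature from the radiation estimate, and the count was then 85 genes. It was 2 without the 41.5 °C array and 2 without the combined one. The BCL2 list was called without the dimmest genes (adjusted p = 0.0224), with the mean of a gene's features (adjusted p = 0.0406), without the 44 °C array (adjusted p = 0.00322) and without the combined 44 °C array (adjusted p = 0.00331), as was the TGF-beta list downward without these arrays (adjusted p = 0.0213 and 0.0216). Without both 44 °C arrays, a fit added after the data were seen, 87 genes were called, of which 41 rose and 46 fell. SESN1 rose 2.69-fold (1.43 ± 0.11, adjusted p = 1.1e-04), TP53INP1 2.96-fold and GDF15 2.54-fold, and CENPA fell by 0.97. Of the 19 p53 targets 15 rose over all genes and 19 adjusted over the list alone (median 0.68), and of the 26 G2/M genes 14 and 25 fell (median -0.46). Both lists had adjusted p = 0.818 with an estimated correlation in that fit.

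**Figure D3:**
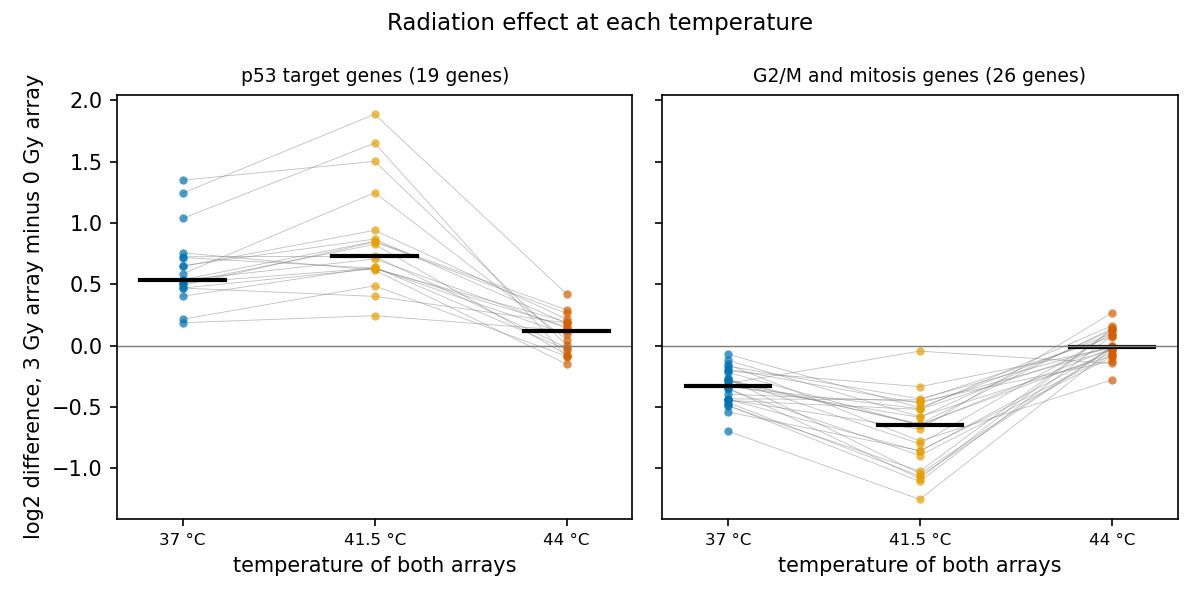
Each point is 1 gene's log2 difference between the irradiated (3 Gy) and unirradiated array at 37, 41.5 and 44 °C (x axis: temperature; y axis: log2 difference), for p53 target genes (19) and G2/M genes (26), with grey lines joining a gene and a black bar at the median. The p53 median was 0.54, 0.73 and 0.12 and the G2/M median -0.33, -0.65 and -0.01 in that order.

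Taken 1 pair of arrays at a time, radiation had different values by temperature. The p53 median was 0.54 at 37 °C and 0.73 at 41.5 °C, both at the 100th percentile of random lists, and 0.12 at 44 °C, at percentile 99.6. The G2/M median was -0.33, -0.65 and -0.01, at percentiles 0, 0 and 3.93. GDF15 had 1.04, 1.65 and -0.09 in these pairs, TP53INP1 1.24, 1.89 and 0.42, and CENPA -0.70, -1.25 and -0.03. Adding radiation to 41.5 °C gave 73 genes at least 2-fold apart (30 higher, 43 lower), and adding it to 44 °C gave 18 (10 higher, 8 lower), which became 25 and 3 without the dimmest genes. A test of radiation at 44 °C against radiation at the lower temperatures, added after the data were seen, called 5 genes (910 at an unadjusted p under 0.05). At 44 °C that test had a single pair of arrays, so its spread came from the other 4 arrays and its p-values do not measure how far a 44 °C array could deviate by itself. The p53 list was lower by that test in 19 of 19 members (median -0.58, adjusted p = 3.6e-26) and the G2/M list higher in 26 of 26 (median 0.56, adjusted p = 6.8e-24), both with adjusted p = 0.817 with an estimated correlation.

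The combined treatments were also set against the sum of heat and radiation alone. The departure reached 2-fold in 192 genes at 41.5 °C (87 higher, 105 lower) and in 154 at 44 °C (66 higher, 88 lower), of which 37 and 32 were left without the dimmest genes. These values rest on 4 single arrays each, have no replicate check and share the control and irradiated arrays. At 41.5 °C the p53 median departure was 0.22 (percentile 99.99, 16 of 19 higher) and the G2/M median -0.40 (percentile 0). At 44 °C they were -0.44 (percentile 0, 19 of 19 lower) and 0.39 (percentile 100). The highest departures at 41.5 °C were those of MIR365A (1.53), DPY19L3-DT, SNAR-D, LHX1 and SNAR-C1, and the lowest those of MIR891A (-1.38), FAM238C, MIR548H2, MIR4481 and MIR4710. At 44 °C the highest were VTRNA1-1, a vault RNA (1.49), MIR365A, MIR421, ZNF224 and MIR4295, and the lowest SESN1 (-1.35), MIR3189, MIR191, MIR4710 and GDF15 (-1.13).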

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

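Apart from the count of genes over other splits of the arrays, the tests in this part were chosen after the results they bear on were seen, and so was the test of radiation at 44 °C against radiation at the lower temperatures.

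Signal in features that the comparisons leave out was found at 44 °C. Of the 37519 features without a gene name here, 1213 were called higher and 280 lower at 44 °C than at 37 °C in the same limma model, 882 of them at least 2-fold higher, and the largest difference was 6.99 on the log2 scale. At 41.5 °C, 5 were called higher and 1 lower. The median level of these features was 4.03 over the 6 arrays, against 5.40 for named genes in the control array.

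Several results stood out because the radiation response at 44 °C had values apart from those at 37 °C and 41.5 °C in a test of the difference itself. That test has a single pair of arrays at 44 °C and 1 residual degree of freedom, which comes from the other 4 arrays, so its p-values do not measure how far a 44 °C array could deviate by itself. For SESN1 the difference was -1.42 ± 0.19 on the log2 scale, for GDF15 -1.44 ± 0.20 and for PCNA-AS1, antisense to a replication clamp gene, -1.10 ± 0.16. CLU, the extracellular chaperone clusterin, had 1.06 ± 0.14 and VTRNA1-1 had 1.64 ± 0.23. Each of these 5 genes had adjusted p = 0.0392 in limma, and they were named because they passed. Among the lists, the p53 targets had a median of -0.58, the G2/M genes 0.56 and the BCL2 family -0.22, the last with adjusted p = 0.0485, and all 3 had adjusted p = 0.817 with an estimated correlation.

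The first pattern weighed is the smaller radiation response of the p53 and G2/M lists at 44 °C. Loss of the p53 targets in dim signal was argued against, since all 19 measured were above the dimmest range in the 44 °C array. The change with 44 °C alone was 0.187 of the change with radiation alone for the median of the p53 targets and 0.452 for that of the G2/M genes. These ratios rest on single arrays that share the control and have no spread between arrays, so whether heat alone had already moved the lists stays open. An exchange of a 44 °C array with a cooler one was argued against, since the heat shock median against the control was higher by at least 1.03 in the 44 °C arrays than in any cooler array, while arrays of 1 temperature differed by at most 0.10. An exchange of both 44 °C arrays would turn the sign of the response and leave its size. Also open are whether less or no radiation reached that culture, whether either 44 °C array deviated by itself, and whether heat at 44 °C delayed or blunted the response, which is a hypothesis.

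The next pattern is the inflammatory NF-kappaB list, which was higher at 41.5 °C than at 44 °C. A single deviating array was argued against at the preset correlation, where the highest adjusted p of the list over the 6 refits without 1 array was 1.0e-06, although with an estimated correlation the list was not called in the fit of all 6 arrays (adjusted p = 0.231). A response of these genes limited to mild heat may account for the pattern, as a hypothesis, and a loss of short-lived transcripts at 44 °C stays open.

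The last pattern is the number of microRNA features that were lower at 44 °C than at 37 °C, 50 of 1072, against 29 higher. Over all genes tested, 4.66% of microRNA features fell, against 2.34% of protein-coding genes and 4.47% of transcribed pseudogenes, so the excess was not particular to microRNA features. At 44 °C against 41.5 °C it was absent, with falls in 7.09% of microRNA features and 7.77% of protein-coding genes. The number of falls over all genes depended on scaling and on the arrays kept, and the microRNA features were not counted again under those settings. Noise of the dimmest features alone would have left brighter ones without an excess of falls. Among genes above the dimmest range, 28 of 350 microRNA features fell (8%) against 274 of 8820 protein-coding genes (3.11%), a ratio of 2.58 (two-sided Fisher's exact test over genes, p = 1.8e-05). The 2 kinds were not matched on level, and over all genes tested their median levels were 3.59 and 5.75. Noise at low signal therefore stays open, and the test treats features of the same arrays as independent. Of the 33 called microRNA features inside 1 measured gene, 81.8% had the sign of that gene. This was above the 95th percentile (66.7%) of shares with genes drawn at random, so these features may follow transcription of the genes they lie in. The genes were found by position alone, so a microRNA on the opposite strand counted as inside, and the share is not a measure of their transcription. Of the 33, however, 6 lay in a gene that was itself called, and the other signs came from values that did not pass. MIR27B and MIR23B lie in AOPEP, which fell by 0.99 (adjusted p = 2.1e-04), whereas MIR21 lies in VMP1, whose value was -0.16 (adjusted p = 0.217). Whether the mature microRNAs changed was not tested.

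The radiation calls were set against other splits of the 6 arrays into 3 and 3, with temperature kept in the model. These make 10 splits, too few for a share under 0.05, and the other splits are built from the same pairs of irradiated and unirradiated arrays, so they hold the radiation response too. The real split gave 0 called genes in limma, with 733 at an unadjusted p under 0.05, and the highest of the others gave 0. For lists the real split gave 3 and the highest other 4.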

How the results depend on the processing

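The refit and the count without both 44 °C arrays were chosen after the data were seen, and the other alternatives in this part were planned. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers that groups share, beyond the temperature term, which sets irradiated against unirradiated arrays of 1 temperature. Over all alternatives, 1387 list values stayed on their side of the threshold, 73 lost the call, 24 gained it and 4 reversed in the test's direction with a call before or after. For named genes 6451 stayed, 318 lost the call, 157 gained it and 1 reversed. Of the values that stayed, 94 list medians and 161 gene values changed sign, in lists and genes that were not called. A median also changed sign in 1 list that lost the call and 2 that gained it. All 5 reversals came from leaving out 1 array. The G2/M list at 41.5 °C against 37 °C had a median of -0.0046 (adjusted p = 0.731) without the combined 41.5 °C array, with the test pointing up, in a range of -0.53 to -0.0046 over the refits. The others were not called with all 6 arrays and were called in the refit: the p53 targets without the combined array at 44 °C (0.15, range -0.27 to 0.15) and at 41.5 °C (-0.16, range -0.16 to 0.28), each against 37 °C, the G2/M list at 44 °C against 37 °C without the combined array (-0.25, range -0.25 to 0.21), and GDF15 at 44 °C against 41.5 °C without the 44 °C array (-0.64, range -0.64 to 0.79). Calls shared with a further quantile normalization were 863 at 44 °C against 37 °C, with 0 in the opposite direction. The number of arrays limits all counts. Except where fewer arrays were fitted or the threshold itself was moved, the cause was not tested.

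For 44 °C against 37 °C, 41.5 °C against 37 °C and 44 °C against 41.5 °C, in that order, the called genes were 405, 9 and 791 without the intensity trend, 192, 29 and 225 with a change of at least 2-fold, and 3054, 2545 and 3777 at an unadjusted p under 0.05. Leaving out each array in turn gave 263 to 1212, 19 to 800 and 1024 to 1299. Fitting only the 4 arrays compared gave 800 at 41.5 °C against 37 °C. For radiation the count was 1 after median centring, 2 without the dimmest genes, 1 with the mean of a gene's features, 733 at an unadjusted p under 0.05, 87 without both 44 °C arrays and 0 to 85 without each array in turn.

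With an estimated correlation 0 lists were called in any of the 4 comparisons. That test had only 2 residual degrees of freedom, so this does not show that correlation undid the calls. The correlation estimated from the residuals, which also hold the interaction, was 0.93 for the p53 targets and 0.83 for the G2/M genes. The next highest was 0.36, for the mitochondrial chaperones and proteases, and the heat shock list had -0.03. For the p53 and G2/M lists the preset of 0.01 is therefore doubtful, and their camera p-values at that preset may be far too small. By fry 3, 3 and 6 lists were called between temperatures, in the same order, and 1 for radiation. The G1/S genes were called by fry in all 4 comparisons, whereas the p53 and G2/M lists had adjusted p = 0.627 by fry for radiation. Leaving out each array in turn gave 5 to 11, 5 to 8 and 7 to 12 lists, and 2 to 5 for radiation, where 5 were called without both 44 °C arrays.

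At 1.5-fold and 3-fold in place of 2-fold, the genes that differed from the control were 450 and 0 for radiation alone, 614 and 4 for 41.5 °C, 1073 and 73 for 44 °C, 864 and 7 for 41.5 °C with radiation, and 965 and 69 for 44 °C with radiation. For radiation added to heat they were 492 and 3 at 41.5 °C and 272 and 1 at 44 °C, and for departures 1142 and 15 at 41.5 °C and 1116 and 17 at 44 °C. Without the dimmest genes, the 2-fold counts against the control were 9 for radiation alone, 28 for 41.5 °C and 68 for 41.5 °C with radiation. They were 25 and 3 for radiation added to 41.5 °C and 44 °C, against 73 and 18 with all genes. For departures at these temperatures they were 37 and 32, against 192 and 154 with all genes. Most of the 2-fold departures therefore lay among the dimmest genes, and the cause was not tested.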

Other observations

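The BCL2 family of apoptosis genes was not called as a list at 44 °C against 41.5 °C, with 3 higher, 1 lower and 10 of 14 not called (median -0.02, adjusted p = 0.676). Its member BCL2A1, a survival factor, rose by 1.17 at 41.5 °C against 37 °C, a call lost without the control (adjusted p = 0.0644) or the irradiated array, and was lower at 44 °C than at 41.5 °C by a log2 difference of -1.51. MCL1, another survival factor, and the death factor BCL2L11 were higher at 44 °C than at 41.5 °C, by 0.91 and 1.22. SKIL, a brake on TGF-beta signalling, was higher there by 0.75 and TP53I3, an oxidoreductase induced by p53, fell by 0.99. CD14 and CD68, markers of monocytes and macrophages that epithelial lines can also transcribe, were higher by 0.77 and 0.56, in a leukocyte list of 5 that was not called (adjusted p = 0.0616). These calls at 44 °C against 41.5 °C held without any 1 array.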
